A study of Mus musculus with 6 samples.

How the data were processed

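RNA was measured in microglia, the resident macrophages of the brain, sorted by flow cytometry from the cortex of 6 female mice aged 20 months. Per the labels, 3 mice carried floxed Atg7 alleles only and 3 carried the floxed alleles together with a Cre recombinase that removes Atg7 in microglia. The sample titles give this Cre allele as Cx3cr1-CreERT2. Live cells with intermediate CD45 and positive CD11b staining were collected into lysis buffer. Per the labels' protocols, cDNA was made with a SMARTer Ultra Low kit, sheared by sonication, ligated to adapters and amplified by PCR. No molecular identifiers were mentioned, so reads are not independent molecules, and the floors given here cover counting error only. The labels give each library its own biological replicate number.

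The deposited table holds whole-number read counts per gene, not normalized, per the file headers and the values. Per the submitters' processing notes, bcl2fastq, STAR, Subread, featureCounts and Salmon were used with the genome build GRCm39. The versions in those notes are not used here, because citation digits appear attached to them, and the strand setting of the counting is not given in the sources used here. The notes name GRCm39, whereas 55141 of the 55487 Ensembl identifiers (99.4%) were found in GENCODE M21, an annotation of the preceding mouse assembly, so no coordinates are printed. The table had 55774 rows, of which 287 repeated an identifier and were left out. The number of rows naming no gene was 0, and 0 columns belonged to other samples.

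Library totals were 39389527, 38798703 and 1254380 reads for controls 1 to 3 and 33129233, 3789208 and 21282335 reads for knockouts 1 to 3. A floor of 3 reads corresponded to between 0.0762 CPM in control 1 and 2.39 CPM in control 3. Control 3 and knockout 2 are called the shallow libraries below.

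Differences between the groups were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: genes were kept by its default expression filter, libraries were scaled by TMM, and a robust quasi-likelihood F-test was fitted with the group as the only term. Of the genes, 15787 were tested, 12000 of them protein coding. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors are the size of the coefficient divided by the square root of the F statistic, and CPM values are TMM-scaled. The text calls knockout over control a log2 fold change; a positive value is higher in the knockout. Mean CPM values are given with the SD of 3 libraries.

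Gene lists for autophagy, stress, ferroptosis, microglial states, metabolism and other cell types, 33 in number, were fixed from textbook knowledge and the study's title before the data were examined. They were tested with camera from limma 3.58.1, two-sided, with a preset correlation between genes of 0.01, where at least 3 members were measured, and adjusted over the 31 lists tested. The same test with an estimated correlation, and fry, were alternatives. Each count of list members is given over all genes tested and adjusted over the list alone.

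Genes were named by a rule fixed before the data were examined. It takes Atg7 and Cx3cr1; in each direction the 12 called genes with the largest fold change, a mean of at least 5 CPM and no overlap between the groups, filled where fewer passed with the smallest unadjusted p; and in each list up to 4 called members or, with none called, up to 2 with the smallest p. Predicted genes and pseudogenes were not named under the rule. List members past the threshold adjusted over the list alone are also named, and any other gene is described as chosen after its value was seen. The share of exonic bases in common with other genes was computed for the genes of the rule from GENCODE M21.

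The steps were tested on simulated data. Counts were drawn for 15787 genes from the means, totals and fitted dispersions of these libraries, with 100 genes changed by log2 1 and 100 by log2 2. These changed genes had a mean of at least 5 CPM and lay outside all lists, so recovery at lower levels was not measured. The edgeR test then ran on 14981 genes. It recovered 9% of the changes of log2 1 and 74% of those of log2 2, with 11 false calls among 94, and 4.34% of unchanged genes had an unadjusted p under 0.05. In the same simulation 1 list of the 29 lists measured was shifted by -0.4. Camera with the preset correlation called that list (adjusted p = 0.00211) and 0 of the 27 unshifted lists that share no member with it. The simulated genes were drawn independently of each other. The list results therefore do not show how camera performs where members are correlated.

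Alternatives set before the data were examined were DESeq2 size factors or library totals in place of TMM, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 50 reads), protein-coding genes alone, DESeq2 1.42.0, limma voom, edgeR without the robust option, the replicate number as a block, other thresholds, lists without shared members, and each library left out in turn. After the data had been seen, 3 alternatives were added: both shallow libraries left out together, all libraries thinned to the shallowest total, and limma voom with a weight per library.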

Results

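The data were read counts from cortical microglia of 6 aged female mice, 3 with floxed Atg7 alleles (controls) and 3 in which Cre recombinase driven from the Cx3cr1 locus removed Atg7 in microglia (knockouts). Atg7 encodes the enzyme that starts the conjugation of LC3 and ATG12 during autophagosome formation. The control mice carried no Cre, so loss of Atg7 and presence of the Cre allele were varied together. Treatment of the mice and the time since deletion are not given in the sample titles. Depth was uneven. Control 3 held 1254380 reads and knockout 2 held 3789208, against 21282335 to 39389527 reads in the other 4 libraries. The log2 CPM values of controls 1 and 2 had a Pearson correlation of 0.965 across genes, and control 3 had a correlation of 0.814 with control 1 and 0.818 with control 2; genes are not independent replicates. Counts of each pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 39.4 or more.

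The labels were first checked with the targeted gene. Atg7 (ENSMUSG00000030314) fell from 62.9 CPM ± 5.46 (SD, n = 3) in the controls to 25.1 CPM ± 1.39 in the knockouts, a log2 fold change of -1.33 (SE 0.19, edgeR adjusted p = 0.0147). All 3 knockout libraries, at 25.0, 26.5 and 23.7 CPM, lay below all 3 control libraries, at 65.7, 66.4 and 56.6 CPM. Exons outside the deleted part of Atg7 are still counted, so the remaining reads do not measure functional transcript. Cx3cr1 (ENSMUSG00000052336), the fractalkine receptor gene whose locus carries the Cre, fell from 10620 CPM ± 907 to 4710 CPM ± 791, a log2 fold change of -1.17 (SE 0.13, edgeR adjusted p = 0.00126). Because the Cre allele sits at this locus, the fall of Cx3cr1 cannot be read as an effect of Atg7 loss. The Atg7 call was lost, with edgeR adjusted p-values of 0.0527 to 0.135, when any one library other than control 3 was left out, although its log2 fold change stayed between -1.41 and -1.29.

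The main comparison asked how the transcriptome of microglia differs between the knockouts, with loss of Atg7 and the Cre allele, and the controls. Beyond Atg7 and Cx3cr1, edgeR called 5 genes, all of them higher in the knockouts. Other tools and settings, given below, called further genes, some of them lower. Esr1, the estrogen receptor alpha gene, rose from 8.54 CPM ± 2.84 (SD, n = 3) to 387 CPM ± 49.1, a log2 fold change of 5.60 (SE 0.24, edgeR adjusted p = 8.3e-09). The Cre in this mouse line is fused to a ligand-binding domain derived from ESR1, and reads of that fusion and of Esr1 were not separable in gene counts. Wfdc17, a gene for a secreted whey acidic protein domain protein of activated macrophages, rose from 1.76 CPM ± 1.23 to 22.9 CPM ± 11.6, a log2 fold change of 4.16 (SE 0.56, edgeR adjusted p = 0.0147). Its values were 0.789, 1.34 and 3.14 CPM in controls 1 to 3 and 33.7, 24.2 and 10.7 CPM in knockouts 1 to 3. In the same order the summed markers of border-associated macrophages, described below, were 15.0, 40.4 and 90.4 CPM and 257, 164 and 66.6 CPM, so that Wfdc17 ranked the libraries within each group as these markers did.

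The other genes called higher were Osgin1, Slc39a4 and Blvrb. Osgin1 is an oxidative stress response gene, Slc39a4 is a zinc importer gene, and Blvrb encodes the biliverdin and flavin reductase of heme breakdown. Osgin1 went from 14.8 CPM ± 0.79 to 44.8 CPM ± 11.6 (log2 fold change 1.61, SE 0.24, edgeR adjusted p = 0.0194). Slc39a4 went from 29.3 CPM ± 1.85 to 82.6 CPM ± 16.5 (1.49, SE 0.20, adjusted p = 0.0109), and Blvrb from 63.8 CPM ± 8.05 to 140 CPM ± 25.3 (1.13, SE 0.18, adjusted p = 0.0409). In each of these 5 genes the 3 knockout libraries lay above the 3 control libraries.

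**Figure D1:**
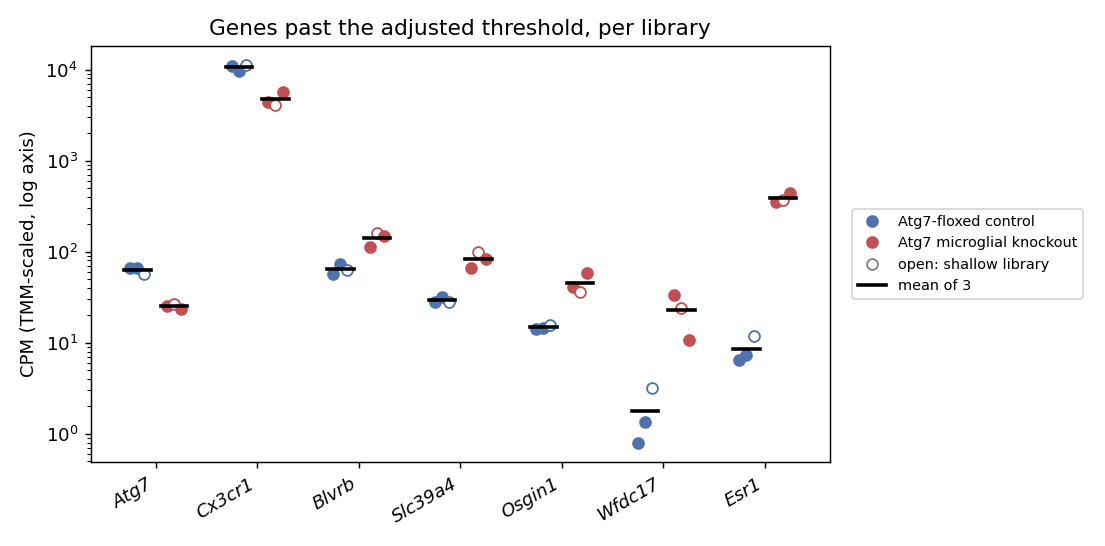
CPM per library, on a log axis, of the 7 genes past the adjusted threshold in the 3 Atg7-floxed control and 3 Atg7 knockout libraries; bars are means of 3 and open circles mark the shallow libraries, control 3 and knockout 2. The groups do not overlap in any of the 7 genes, and Esr1 lies at 6.49 to 11.8 CPM in the controls and 349 to 443 CPM in the knockouts.

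In all, edgeR called 5 genes higher and 2 lower of 15787 tested. At an unadjusted p under 0.05, 370 genes were higher and 312 lower; DESeq2 called 49 higher and 34 lower, and limma voom 9 and 6. The groups did not overlap in 1745 genes, 11.1% of those tested, where chance gives 10%. The counts rested on the libraries used: without control 3 they were 15 higher and 35 lower, without control 1 or knockout 2 they were 1 and 1, without knockout 1 they were 2 and 1, without knockout 3 they were 8 and 1, and without control 2 they were 5 and 1. With both shallow libraries left out, an alternative added after the data had been seen, 9 genes were higher and 30 lower. Esr1 and Cx3cr1 were called in each of these fits. Of the other genes, the calls of Wfdc17, Osgin1, Slc39a4 and Blvrb were lost without control 1 or knockout 2. Those of Wfdc17, Osgin1 and Blvrb were lost without control 2 or knockout 1. Without knockout 3 the calls of Osgin1 and Blvrb were lost, and without both shallow libraries that of Blvrb. Limma voom did not call Wfdc17 and Blvrb (adjusted p = 0.0745 and 0.0659), and thinning to the shallowest total lost Wfdc17 and Osgin1. Wfdc17, Osgin1, Slc39a4 and Blvrb were all lost in edgeR without the robust option and in voom with library weights.

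Several further genes ranked next without passing the adjusted threshold, and their values are given as such. On the higher side, Dab2, an endocytic adaptor gene, had 27.9 CPM ± 4.73 in the controls and 74.0 CPM ± 24.7 in the knockouts (log2 fold change 1.40, edgeR adjusted p = 0.0635). Cdkn1a, which encodes the cell cycle inhibitor p21, had 15.8 CPM ± 4.64 and 46.1 CPM ± 15.1 (1.50, adjusted p = 0.129). Trpv4, a calcium channel gene, Tmem205, the adhesion gene Vcam1, Anxa2 and the lectin gene Mgl2 had log2 fold changes of 1.18, 1.27, 1.11, 2.15 and 3.00, with edgeR adjusted p-values from 0.12 to 0.179. On the lower side, Calr, which encodes the endoplasmic reticulum chaperone calreticulin, had 585 CPM ± 63.1 in the controls and 321 CPM ± 38.3 in the knockouts (-0.87, adjusted p = 0.0623), and Pdia6, a disulfide isomerase gene, had 833 CPM ± 46.9 and 499 CPM ± 77.2 (-0.74, adjusted p = 0.139). The orphan receptor gene Gpr165, the cytochrome c oxidase gene Cox5a, Trp53i13, Klhdc8b, H2-Oa, Cog8, Uck1 and Serpinf1 had log2 fold changes of -1.23, -1.93, -2.40, -1.10, -0.86, -1.68, -1.40 and -1.01, with edgeR adjusted p-values from 0.122 to 0.244. In the GENCODE M21 annotation Cog8, H2-Oa, Trp53i13 and Cox5a share 28.2%, 22.8%, 15.2% and 12.8% of their exonic bases with another gene, so the assignment of their reads is uncertain. Of the genes named below the same holds for Gabarapl1 (28.3%), Sqstm1 (17.3%), Pkm (15.3%) and Aldh1l1 (13.4%). DESeq2 gave adjusted p-values under 0.05 for all 17 of these genes that ranked next. Limma voom did so only for Trpv4, Tmem205, Anxa2, Calr, Cox5a, Trp53i13 and Uck1, with a highest adjusted p of 0.259 for Mgl2.

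Genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, were lower in the knockouts as a group when tested with the preset correlation. The list was called lower by camera (adjusted p = 6.2e-10), but not with an estimated correlation (adjusted p = 0.408). Against control 3 alone, a fit chosen after the data had been seen, the median was -0.16 and the list was not called (camera adjusted p = 0.186); that control is 1 shallow library, so the spread came from the knockouts only. Of 30 measured members, 27 had a log2 fold change below 0, the median was -0.30, and the summed level was 9526 CPM in the controls and 6230 CPM in the knockouts. The chaperone genes Hspa5 (1600 CPM ± 177 against 980 CPM ± 278), Hsp90b1 and Calr and the disulfide isomerase genes Pdia3, Pdia4 and Pdia6 were among the 10 members lower when adjusted over the list alone, with Canx, Manf, Dnajc3 and Sdf2l1. The sums were 10039, 9710 and 8828 CPM in controls 1 to 3 and 6950, 5633 and 6108 CPM in knockouts 1 to 3. The stress transcription factor genes Atf4 and Ddit3 had log2 fold changes of 0.06 (SE 0.23) and -0.27 (SE 0.39); they were chosen after their values were seen.

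Over all genes tested, edgeR called 0 members of the unfolded protein response list, with 13 lower and 0 higher at an unadjusted p under 0.05; DESeq2 called 6 lower and voom 1 lower. The list follows the study's title, so its direction is not independent of what the study set out to report. For Pdia3 and Sdf2l1, control 3 lay between the other controls and the knockouts. Pdia3 had 1839, 1591 and 1025 CPM in controls 1 to 3 and 733, 658 and 363 CPM in knockouts 1 to 3. In the same order Sdf2l1 had 200, 199 and 108 CPM and 78.9, 86.2 and 44.0 CPM. In Pdia6 and Calr, control 3 lay nearer to the other controls than to the knockouts. Pdia6 had 790, 883 and 825 CPM and 541, 410 and 545 CPM, and Calr 579, 651 and 525 CPM and 360, 283 and 319 CPM. These genes were picked out after their values were seen.

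**Figure D2:**
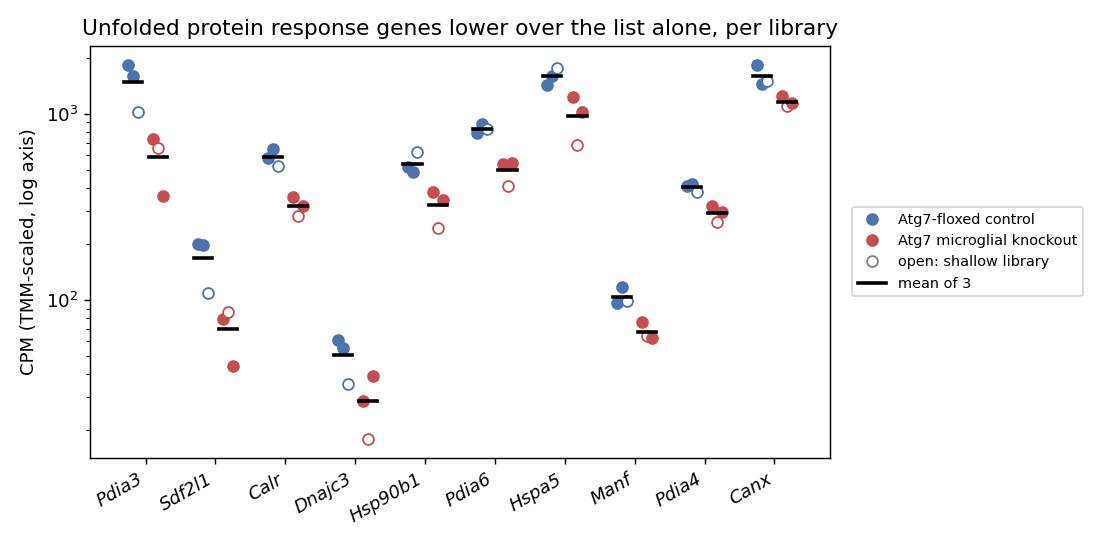
CPM per library, on a log axis, of the 10 unfolded protein response genes that were lower when adjusted over the list alone, in 3 control and 3 knockout libraries; bars are means of 3 and open circles mark control 3 and knockout 2. Each gene lies lower in the 3 knockout libraries than in the 3 control libraries except Dnajc3, where knockout 3 lies above control 3.

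Targets of NRF2, the transcription factor of the antioxidant response, were higher in the knockouts as a group when tested with the preset correlation. The list was called higher by camera (adjusted p = 7.7e-10), but not with an estimated correlation (adjusted p = 0.408). All 23 measured members had a log2 fold change above 0, with a median of 0.45, and Osgin1 and Blvrb passed over all genes tested. Adjusted over the list alone 6 members were higher, which adds Mgst1, Fth1, Taldo1 and Prdx1. Fth1, the ferritin heavy chain gene, had 2999 CPM in the controls and 4487 CPM in the knockouts (log2 fold change 0.58, SE 0.16). The list's summed CPM was 5655, 6094 and 4382 in controls 1 to 3 and 7797, 8502 and 6735 in knockouts 1 to 3. In the same comparison the summed markers of border-associated macrophages went from a mean of 48.6 CPM to 163 CPM. Those of monocytes went from 35.0 CPM to 90.9 CPM. Per library the border macrophage sums were 15.0, 40.4 and 90.4 CPM in the controls and 257, 164 and 66.6 CPM in the knockouts. The monocyte sums were 10.7, 46.3 and 47.9 CPM and 174, 74.3 and 24.7 CPM in the same order. Control 3 had the highest marker sums of the controls but their lowest NRF2 sum. Knockout 3 had the lowest of each among the knockouts. The low NRF2 sum of control 3 was not particular to that list. Its sums of autophagy core machinery, nuclear-encoded oxidative phosphorylation and proteasome genes were also the lowest of the controls, while that of inflammatory genes was the highest. Against control 3 alone, a fit chosen after the data had been seen, the NRF2 median was 0.93. That value rests on 1 shallow library with low sums in these other lists too.

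Ferroptosis, an iron-dependent death by lipid peroxidation that the study's title names, was covered by lists of drivers and of defence genes. Defence and iron storage genes were called higher (15 of 20 members above 0, median 0.27, camera adjusted p = 0.0275; adjusted p = 0.408 with an estimated correlation). Of these members 9 stand also in other lists, and the call was lost when shared members were removed (adjusted p = 0.596), when control 1, control 3, knockout 1 or knockout 2 was left out (0.067, 0.106, 0.123 and 0.0796) and without both shallow libraries (0.13). EdgeR called 0 members, with 3 higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, and 0 called by DESeq2 or voom; Fth1 and Prdx1 (0.45, SE 0.15) had the smallest p. Drivers and iron uptake genes were not called (median 0.15, adjusted p = 0.254): 11 of 17 members were above 0, and edgeR, DESeq2 and voom each called 0, with 1 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone, the 5-lipoxygenase gene Alox5 (log2 fold change 0.58, SE 0.16). Cybb had a log2 fold change of 1.13 (SE 0.54), and of 0.55 to 1.38 with a library left out. Reads of ferritin genes can be shared with their pseudogenes, and the macrophage and monocyte markers given above for NRF2 targets had higher means in the knockouts.

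The medians of microglial state genes shifted little. Homeostatic microglia genes were called lower (19 of 22 members below 0, median -0.23, camera adjusted p = 0.0135; adjusted p = 0.726 with an estimated correlation), with Cst3 at -0.30 (SE 0.11), while P2ry12, chosen like Trem2 and Apoe below after its value was seen, had -0.03 (SE 0.10). Disease-associated microglia genes were called higher (15 of 24 members above 0, median 0.09, camera adjusted p = 0.0178; adjusted p = 0.742 with an estimated correlation), with Lyz2 at 0.95 (SE 0.23) and Cst7 at 0.74 (SE 0.23); Trem2 had -0.10 (SE 0.15) and Apoe 1.22 (SE 0.52). Lyz2 reads can be shared with its paralog Lyz1. The summed CPM of the homeostatic list did not overlap between the groups. It was 115600, 113898 and 98360.5 in controls 1 to 3 and 96920, 90335 and 94876 in knockouts 1 to 3. That of the disease-associated list overlapped, at 24792, 28825 and 23157 in controls 1 to 3 and 28239, 26199 and 27706 in knockouts 1 to 3. The macrophage and monocyte markers given above for NRF2 targets had higher means in the knockouts. EdgeR called 0 members of either list; at an unadjusted p under 0.05, 6 homeostatic members were lower, and 6 disease-associated members were higher and 1 lower. Adjusted over the list alone 0 homeostatic members and 1 disease-associated member passed, DESeq2 called 0 and 1, and voom 0 and 0. The homeostatic call was lost without control 1, control 2 or knockout 2 (adjusted p = 0.127, 0.0563 and 0.0796), and the disease-associated call without control 1, control 3, knockout 1 or both shallow libraries (0.597, 0.0575, 0.144 and 0.0689) and without the 8 members that stand also in other lists (0.0904).

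Antigen presentation genes were called higher (14 of 18 members above 0, median 0.25, camera adjusted p = 0.000857; adjusted p = 0.656 with an estimated correlation). The MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74 had log2 fold changes of 3.40 (SE 0.72), 2.88 (SE 0.72), 2.05 (SE 0.64) and 2.04 (SE 0.56), chosen with the exception of H2-Eb1 after their values were seen. Cd74 lay at 236, 374 and 343 CPM in controls 1 to 3 and at 2054, 1295 and 559 CPM in knockouts 1 to 3. H2-Oa, which inhibits peptide loading of class II molecules, had 57.4 CPM ± 3.53 and 31.6 CPM ± 2.37. EdgeR called 0 members, with 6 higher and 1 lower at an unadjusted p under 0.05; 1 was lower and 0 were higher adjusted over the list alone, DESeq2 called 3 higher and 1 lower, and voom 0. Without both shallow libraries the camera call was lost (adjusted p = 0.0824). H2 genes are a multigene family whose reads can be shared.

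Markers of other blood and myeloid cells, which the gate on intermediate CD45 and CD11b is meant to leave out, were measured beside these genes. Border-associated macrophage markers were called higher (10 of 10 members above 0, median 2.39, camera adjusted p = 1.5e-10; adjusted p = 0.408 with an estimated correlation), at low levels: their summed CPM was 15.0, 40.4 and 90.4 in controls 1 to 3 and 257, 164 and 66.6 in knockouts 1 to 3. Pf4 had 1.31 CPM in the controls and 10.5 CPM in the knockouts (log2 fold change 2.65, SE 0.64), and Colec12, with 1 read in all controls, had 1.27, 1.82 and 2.37 CPM in knockouts 1 to 3. Monocyte markers were called higher (6 of 7 members above 0, median 1.55, camera adjusted p = 0.00323; adjusted p = 0.656 with an estimated correlation), a call lost without knockout 1 (adjusted p = 0.144). Among them Ccr2 had a log2 fold change of 0.76 (SE 0.45). EdgeR called 0 members of both lists. At an unadjusted p under 0.05, 4 border macrophage and 1 monocyte member were higher; 3 and 1 were higher adjusted over the list alone, DESeq2 called 3 and 1, and voom 0. The neutrophil marker Csf3r had 537 CPM in control 1 and 430 CPM in knockout 1 (log2 fold change -0.22, SE 0.14), and Retnlg had a log2 fold change of 2.91 (SE 1.74). Neutrophil markers were not called with all 6 libraries (camera adjusted p = 0.0638). Their summed CPM, most of it from Csf3r in control 1, ranged from 582 in control 1 to 2441 in knockout 1. They were called higher without control 3, knockout 2, knockout 3 or both shallow libraries (adjusted p = 0.0182, 0.00319, 0.00349 and 3.2e-06), and with no filter, DESeq2, voom with and without library weights and edgeR without the robust option (0.000307 to 0.0499). Without control 1 and without knockout 1 the adjusted p was 0.597 and 0.871. Erythroid markers were not called either (adjusted p = 0.0939), with hemoglobin genes at 34.5 CPM in knockout 3 and at 4.71 CPM or less in every other library. They were called higher without control 3 or knockout 1 (adjusted p = 0.0319 and 0.000778) and with no filter, DESeq2, edgeR without the robust option and the replicate block (0.000975 to 0.0403).

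**Figure D3:**
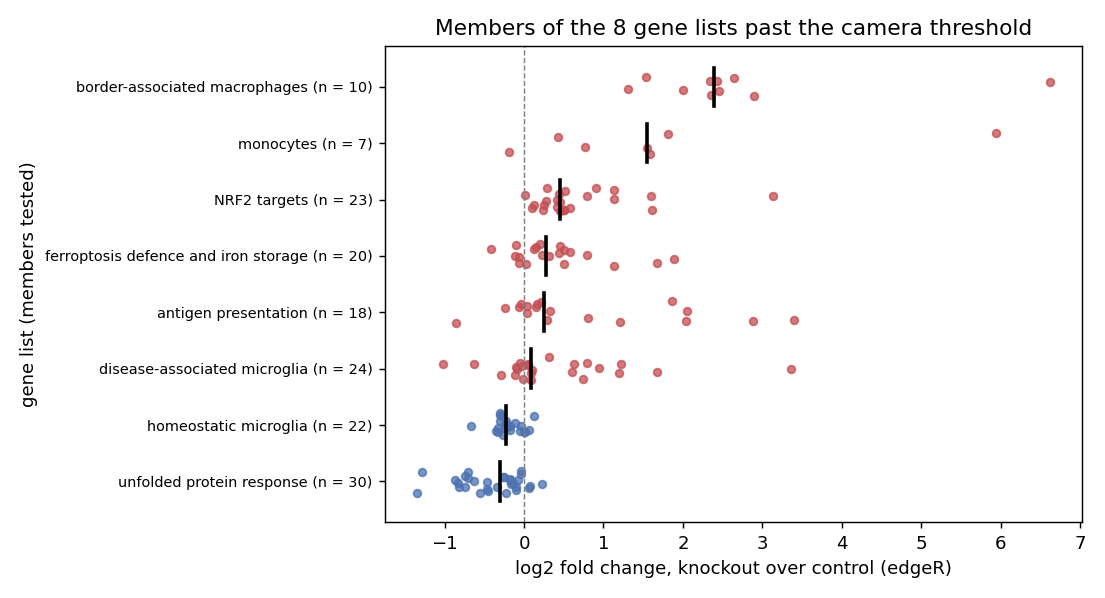
Log2 fold change, knockout over control, of each measured member (points) of the 8 gene lists past the camera threshold; black bars are medians, red lists were called higher and blue lists lower, and n is the number of members tested. The median is 2.39 for border-associated macrophage markers, 0.45 for NRF2 targets and -0.30 for unfolded protein response genes.

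The remaining lists were not called by camera. Over the 23 tested lists without a call, with 381 different members, edgeR called 0 members; 22 were higher and 4 lower at an unadjusted p under 0.05, DESeq2 called 2 higher and 1 lower, and voom 1 lower. Autophagy core machinery without Atg7 had an adjusted p of 0.627 with a median of 0.09; Gabarapl1 had a log2 fold change of 0.67 (SE 0.24) and Atg2a 0.71 (SE 0.29). Selective autophagy receptors, which hand cargo to the autophagosome, had 12 of 12 members above 0 with a median of 0.21 (adjusted p = 0.0588). Among them were Sqstm1 at 0.39 (SE 0.23) and Fundc1 at 0.38 (SE 0.21). With a library left out, these log2 fold changes lay at 0.18 to 0.71 and 0.21 to 0.58. The receptors were called higher without knockout 2 (adjusted p = 0.0325), without both shallow libraries (0.0492), and with library totals, the stricter filter, protein-coding genes, DESeq2 and voom with and without library weights (0.0054 to 0.0366). Lysosome genes had a median of -0.01 (adjusted p = 0.87), with Glb1 at -0.37 (SE 0.16). Targets of ATF4 had a median of -0.07 (adjusted p = 0.976), with Atf3 at 0.63 (SE 0.28) and Psat1 at 0.51 (SE 0.25); there the mean, 0.08, and the median differ in sign.

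Among immune lists, the type I interferon response had an adjusted p of 0.632 (Oasl2 -0.67, SE 0.33; Cxcl10 0.78, SE 0.50), inflammatory cytokines and NF-kB targets 0.167 (Nfkbia 0.46, SE 0.17; Cxcl2 3.44, SE 0.90, at a mean of 1.29 CPM) and phagocytic receptors 1.0 (Msr1 1.85, SE 0.57; Axl 0.63, SE 0.27). Targets of p53 had an adjusted p of 0.141, with Cdkn1a and Ccng1 (0.80, SE 0.24) higher when adjusted over the list alone. The interferon list was called lower without control 1 (adjusted p = 0.0182) and higher without control 3 (0.0487) or both shallow libraries (0.0265), and with voom without and with library weights (0.0118 and 0.00229). The inflammatory list was called higher without both shallow libraries (0.0375) and with voom without and with library weights (0.0156 and 0.00977), and the dissociation list lower without both shallow libraries (0.0265). The p53 list was called higher without knockout 3 (0.0246), with no filter (0.0434) and with DESeq2 (0.0443), and the lipid storage list higher without control 2 (0.0314). For metabolism, the adjusted p was 0.976 for cholesterol biosynthesis (Dhcr7 0.42, SE 0.19; Stard4 1.43, SE 0.73), 0.254 for lipid storage and efflux (Lipa 0.61, SE 0.15; Acsl1 -0.49, SE 0.21), 0.87 for nuclear-encoded oxidative phosphorylation (Cox5a; Cox4i1 0.39, SE 0.17) and 0.632 for glycolysis (Aldoa 0.38, SE 0.14; Pkm 0.37, SE 0.14). The adjusted p was 0.87 for the proteasome (Psmb4 0.29, SE 0.23; Psmb3 -0.21, SE 0.17), 0.632 for the cell cycle (Bub1 2.22, SE 0.97; Mcm6 -0.64, SE 0.35), 0.87 for immediate early genes of dissociation stress (Jun -0.57, SE 0.27) and 0.254 for mitochondrially encoded genes (mt-Co3 0.45, SE 0.19; mt-Co2 0.49, SE 0.22).

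Markers of neurons, astrocytes, oligodendrocyte lineage cells and endothelial cells had adjusted p-values of 0.976, 0.87, 0.427 and 0.632, with Aldh1l1 at 1.47 (SE 0.50), Slc1a2 at -0.68 (SE 0.47), Mobp at 1.17 (SE 0.54), Mbp at 0.48 (SE 0.22) and Pecam1 at -0.43 (SE 0.31). Lists of T and NK cells and of B cells had 1 and 2 measured members and were not tested; Lck had a log2 fold change of -1.95 (SE 1.01), Cd79b -0.35 (SE 0.17) and Ighm -0.15 (SE 0.15).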

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

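The added alternatives (both shallow libraries left out, thinning and voom with library weights) were chosen after the data had been seen. Esr1 and Cx3cr1 were called in all 18 alternatives that give gene values. Genes higher, 5 in the report, numbered 60 with no filter, 49 with DESeq2, 9 with limma voom, 1 in edgeR without the robust option, 9 without both shallow libraries, 8 after thinning, 2 with voom weights, and 1 to 15 when each library was left out. Genes lower, 2 in the report, numbered 42, 34, 6, 1, 30 and 6 in the first 6 of these settings, and 1 to 35 with a library left out. The Atg7 log2 fold change was -1.33 without the robust option and -1.41 to -1.29 with a library left out; its call was lost in these except without control 3. Lists higher, 6 in the report, numbered 10 with DESeq2, 11 with voom, 10 with voom weights, 0 with an estimated correlation and 0 with directional fry; lists lower, 2 in the report, numbered 0 and 0 in these last 2 and 1 to 2 with a library left out. Mixed fry, which tests no direction, called 2 lists, NRF2 targets and nuclear-encoded oxidative phosphorylation. The unfolded protein response had an adjusted p of 0.408 with an estimated correlation, 0.229 with directional and 0.0657 with mixed fry. The ferroptosis drivers reached 0.0358 with voom. Ferroptosis defence had 0.107 with the stricter filter, 0.408 with an estimated correlation, 0.183 and 0.083 with fry, 0.596 without shared members, 0.0321 to 0.123 with a library left out, 0.13 without both shallow libraries and 0.362 after thinning. Psmb4 went from 0.29 to -0.0034 without both shallow libraries. The cause of these changes was not tested. With the replicate number as a block, 16 genes were higher and 9 lower; deviations of same-numbered libraries had correlations of 0.30, -0.22 and -0.06, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Apart from the replicate block, no other setting moved one of these 4 counts by more than the ratio of 3 to 2. Over all results and settings, 1484 values kept direction and side of the threshold or moved little, 90 newly passed, 76 no longer passed, 37 counts moved and 1 value reversed. Depth limits most what control 3 can show, where 3 reads make 2.39 CPM.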

Other observations

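The tests in this part of Esr1, the MHC class II genes, the shallow libraries, control 3 alone, the neighbours without Gm33858 and the ER import list were chosen after the results were seen; the matched lists, the other splits and the 40 neighbours of Cx3cr1 were set before.

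Among genes chosen after their values were seen, Pla2g7, which encodes the lipoprotein-associated phospholipase A2, stood out. It lay at 9.62, 8.28 and 30.6 CPM in controls 1 to 3 and at 163, 192 and 156 CPM in knockouts 1 to 3 (log2 fold change 3.59, SE 0.59), which passed with DESeq2 (adjusted p = 2.3e-05) but with edgeR over all 6 libraries did not (adjusted p = 0.406); without both shallow libraries it did (log2 fold change 4.15, edgeR adjusted p = 1.8e-05). Lipa, the lysosomal acid lipase gene named above, at 346 CPM ± 42.5 (SD, n = 3) and 528 CPM ± 39.2, and the complement gene C4b, at 15.0 CPM ± 7.06 and 53.5 CPM ± 17.6, likewise passed with DESeq2 (adjusted p = 0.00638 and 0.000166) but not with edgeR (adjusted p = 0.261 and 0.406).

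Control 3 and knockout 2 shared a set of genes with high counts. Of 5868 genes with a mean over 20 CPM, 61 lay above the other 4 libraries in both by over 0.9 on the log2 scale, 48 of them protein coding; for the other 14 pairs of libraries this number was 14 or less. The checkpoint gene Rad9b held 30315 CPM in control 3, 10511 CPM in knockout 2 and 342 CPM in knockout 3, against 18.7, 15.4 and 17.5 CPM in controls 1 and 2 and knockout 1. In reads, Rad9b had 38579 in control 3 and 40467 in knockout 2. The 61 genes together took 6.94% of the CPM in control 3, 3.06% in knockout 2, 0.186% in knockout 3 and at most 0.0762% in the other 3 libraries.

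Controls 1 and 2 also stood apart from the other 4 libraries, with 14 genes above all of them by over 0.9 on the log2 scale. Ddost, a subunit gene of the oligosaccharyltransferase, had 333 and 326 CPM in controls 1 and 2, 60.5 CPM in control 3 and 55.6, 72.7 and 53.4 CPM in the knockouts, and Saraf had 564, 503 and 106 CPM against 141, 192 and 116 CPM. All 14 were among the 30 genes called lower by edgeR once both shallow libraries were left out, a fit whose controls are controls 1 and 2 alone. In 28 of the 30, and in 14 of the 16 outside these 14, control 3 lay nearer on the log2 scale to the knockout mean than to the mean of controls 1 and 2. The calls favour genes high in controls 1 and 2, so this tally is no test that these libraries stand apart.

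Esr1 was the called gene with the largest fold. Leaving out both shallow libraries kept its log2 fold change at 5.83 (edgeR adjusted p = 4.0e-06), which argues against these libraries as its source. Reads of the Cre fusion, whose ligand-binding domain derives from ESR1, are a candidate source. Esr1 gained 379 CPM, 6.41% of the 5910 CPM that Cx3cr1 lost. It amounted to 7.94%, 8.98% and 7.89% of the Cx3cr1 CPM in knockouts 1 to 3. A rise of the Esr1 gene itself after loss of Atg7 could give such values too. It stays open, since gene counts do not show which exons were read.

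The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median log2 fold change of 2.47 (median SE 0.68), and border macrophages, which the gate on intermediate CD45 is meant to leave out, may have contributed. With the mean log2 CPM of Mrc1, F13a1, Cd163 and Lyve1 as a covariate, the median was 1.54 (median SE 0.75). Without both shallow libraries it was 2.45 (median SE 1.09). With the covariate the 95% interval from the median SE reached below 0, so carry-over cannot be told apart from a change within microglia; the 4 libraries left without the shallow ones are too few for such an interval to decide, although the median barely moved. Loss of Atg7 as a source was not tested apart from these.

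The lower level of unfolded protein response genes was weighed against library effects. Without both shallow libraries camera with the preset correlation gave an adjusted p of 4.3e-13 with a median of -0.31. That fit, whose controls are controls 1 and 2 alone, cannot address a separate position of those controls. Among 10000 random lists matched on expression, transcript length and GC content 0% had a median as low as -0.30, with a lowest of -0.20. These values argue against the shallow libraries and against length, GC content or expression level as the whole source. A difference of controls 1 and 2 from the other 4 libraries may account for part of it: against control 3 alone the median was -0.16 and the list was not called (camera adjusted p = 0.186), and 1 control library cannot tell how much. Loss of Atg7 and presence of the Cre allele both stay open.

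With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes higher, the real split gave 5 and the highest other split 69, and 2 splits, the real one included here and below, gave as many in either direction; for genes lower, the real split gave 2 and the highest other 69, and 4 splits gave as many. For lists higher, the real split gave 6 and the highest other 11, and 3 splits gave as many; for lists lower, these were 2 and 11, and 6 splits gave as many. The split with 69 genes set controls 1 and 2 and knockout 1 against control 3, knockout 2 and knockout 3, the last 3 being those with more Rad9b reads, and points to a structure of the libraries apart from the groups.

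Passenger sequence carried with the Cre knock-in at Cx3cr1 may come from another strain, and this hypothesis predicts more differences near that locus. Of the 40 tested genes nearest to Cx3cr1, 5 had an unadjusted p under 0.05 (12.5%, against 4.29% elsewhere; Fisher's exact test, two-sided, p = 0.0278): Csrnp1, Gm33858, Mobp, Rpl14 and Lyzl4. EdgeR called 0 of the 40 after adjustment over all genes. Gm33858 (log2 fold change -0.80), with the smallest p of these, is antisense to Cx3cr1 and shares 78 exonic bases with it, and without it 4 of 39 remained (10.3%; Fisher's exact test, two-sided, p = 0.0855). Of the 40 nearest to Atg7, floxed in both groups, 1 had such a p. The share stayed above that elsewhere, but its test passed only with Gm33858; strain was not measured, and the hypothesis stays open.

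A further hypothesis was that genes of protein import and N-glycosylation in the endoplasmic reticulum fell beyond the unfolded protein response list. Of 29 such genes, 25 had a log2 fold change below 0, with a median of -0.28 (camera adjusted p = 5.0e-06 over 32 lists; adjusted p = 0.616 with an estimated correlation), and 7 were lower and 0 higher at an unadjusted p under 0.05. Against control 3 alone the median was 0.01 (camera adjusted p = 0.794), where the spread came from the knockouts only. That 1 shallow control library does not decide between a fall in the knockouts and a separate position of controls 1 and 2, and the list was drawn up after Ddost, Serp1 and Ncln had been seen.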
